A study of Caenorhabditis elegans with 2 samples.

How the data were processed

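EFL-1 chromatin immunoprecipitation and sequencing had been done on whole L1 larvae of a Caenorhabditis elegans strain carrying lin-35(n745), with animals of both sexes pooled, per the labels. There were 2 samples, biological replicates 2 and 3, in 1 group. The labels call them biological replicates and give each its own biological sample, with the same strain source. No extraction protocol was given in the labels. The aligner, the peak caller, the IDR threshold, the read length and the read depth are not given in the sources used here. Depth is therefore unknown, and no value below carries an interval that would need it.

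The data were 8 peak lists in narrowPeak form, 4 on each of 2 genome builds, ce11 and ce10. Per the deposited description texts, each replicate's list was made from its own alignments with a control, keeping strong and weak regions. The joint list was made from both replicates' alignments with a control, and the IDR list from the joint list. The control experiment named in the labels was not used here. The signal value of each peak is the authors' own, on a scale set by their peak caller, and was used only to rank and filter peaks within a list. The −log10 q value of each peak is also the authors' own, and it was the same for all 4534 IDR peaks, so it could not rank them. The summit position was taken from the deposited offset. In 1 IDR peak the offset equalled the width. The 4534 IDR peaks were exactly the 4534 regions of the joint list with the highest signal, which left 17341 weak joint regions. The joint list is labelled as peaks and background. Of its 21875 regions 6596 had a −log10 q value over 2, all IDR peaks among them, so most weak regions may be background. A joint call pools the replicates, so agreement between replicates was measured on their separate lists. Rank correlations used the replicates' own ranks, but only over the IDR peaks.

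All coordinates are ce11, given from 1 as in a genome browser. Genes and sequence came from Ensembl release 115 and the RefSeq assembly of the same build (WBcel235), whose chromosome lengths held every ce11 peak. The ce10 lists were used only for counts, overlaps and shares of peaks, with no conversion of coordinates. In all, 19973 protein-coding genes with 29314 distinct transcript 5' ends on the 6 nuclear chromosomes entered. A gene was called bound if an IDR summit lay from 1000 bp upstream to 500 bp downstream of any of its 5' ends. By this rule 3120 peaks (68.8%) had a gene, and 1031 of them had 2 or more, so a peak between divergent genes counted for both. Annotated 5' ends in this species are often trans-splice sites, and genes inside operons have internal 5' ends with no promoter of their own.

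The share of summits within 500 bp of a 5' end was set against 1000 random placements on the same chromosome. The share of IDR peaks on each chromosome was tested with a two-sided exact binomial test against its share of 5' ends, with Clopper-Pearson intervals. Where a share was 0, the limit in the text is 3 counts of the total, and the figure draws the Wilson interval, which reaches higher. Bound shares of 22 gene lists (14 of named genes and 8 of gene families by symbol) were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. The lists were replication, cell cycle, mitosis, repair, meiosis, germ granule, germline RNA, DREAM and synMuv B, chromatin, cell death, muscle, neuron, intestine, epidermis, ribosomal, proteasome, nuclear pore, histone, major sperm protein, collagen, nuclear hormone receptor and chemoreceptor genes. Of the listed symbols 7 matched no gene of the annotation: pold-1, let-21, rad-54, prg-2, cde-1, mnd-1 and rbbp-4. Odds ratios are sample odds ratios with 95% intervals on the log scale, and 0.5 was added to each cell where 1 was 0. Peak strength was the percentile of a gene's strongest peak in the IDR list. Its median was compared with that of other bound genes by a two-sided permutation test with 100000 resamples, for lists with at least 10 bound genes. In that test the median of the other genes was held at the overall median, since few genes were drawn.

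Matches of 6 sequence patterns on either strand, within 100 bp of the summit, were compared with windows of the same width centred 500 bp to each side. Each pattern was also set against up to 100 letter-shuffled versions with the same bases and the same number of CpG. Replicate agreement was the share of the top 4534 regions of replicate 2 that overlapped 1 of the top 4534 of replicate 3 by at least 1 bp.

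Gene lists, patterns, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took all 8 core genes of the DREAM complex, the 10 genes nearest the strongest peaks, the 3 bound members with the strongest peaks of each list that was called, and 1 of each list that was not. Genes that share a named gene's peak are named beside it where given, chosen after their values were seen. The alternatives were another build, a stricter set of peaks (the stronger 2267), each replicate left out, other windows and distances, nearest genes only, circular shifts of the peaks or of the bound labels, deciles of upstream distance, named genes as background, other motif windows, other control sequences and other overlap rules. A replicate was left out by taking the top 4534 regions of the other replicate's own list. Comparisons of the strongest 454 peaks with the rest within 10 groups of equal GC content, or of CpG count, used Mantel-Haenszel odds ratios. The strongest 454 peaks as a motif set, and the share of genes as the expected share on X, were added after the data were examined.

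The statistics were tested on simulated data. Over 20 simulations, lists bound at 60% against 20% were called in 99.5% of cases and unchanged lists in 3%. There each gene was bound independently, while 1031 real peaks counted for 2 or more genes, so the 3% may not hold for the data. All peaks planted upstream of a 5' end were returned to their gene. They were planted inside the window, so this checks only that the rule was applied. E2F matches planted at 20% of 3000 random sites raised the share from 2.9% to 22.3%, and 2 lists sharing 50% of their peaks gave an overlap of 50.5%. The strength test had little power for moderate shifts. A list raised by 20 percentiles was called in 3 of 20 simulations, and a list raised by 35 in all 20, so a list that was not called can still differ in strength. The simulated lists had more bound genes than most lists tested, where the count ran from 10 to 72. Power for the small lists is therefore lower than these values. The size of the planted shift was raised from 20 to 35 after a first simulation at 20 was not called. Unchanged lists were called 0 and 1 times among 400. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.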

Results

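Binding of EFL-1, a worm member of the E2F family of transcription factors, was mapped by chromatin immunoprecipitation and sequencing in whole first-stage (L1) larvae of Caenorhabditis elegans. The worms came from a strain carrying lin-35(n745), a mutation in the gene for the worm's retinoblastoma-family pocket protein, and were of mixed sex. The series holds 1 group of 2 biological replicates, numbered 2 and 3 in the labels, so binding was described within this strain and no other genotype, stage or antibody was compared. Read totals were not in the peak lists, and the depth of each library is unknown. The authors' joint IDR list (IDR is a test of rank agreement between replicates) held 4534 peaks on the ce11 build, with a median width of 316 bp. The longer joint list from which it was taken held 21875 regions, and the lists of replicates 2 and 3 alone held 25572 and 27203.

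The 2 replicates gave largely the same strong peaks. Of the 4534 strongest regions of replicate 2, 3936 (86.8%, 95% Wilson interval 85.8 to 87.8) overlapped 1 of the 4534 strongest of replicate 3 by at least 1 bp, against 2.58% ± 0.23 (SD of 1000 random placements). The strongest 5 peaks, near tasp-1, T23F6.3, F48A11.4, cdc-48.1 and dld-1, held the same ranks, 1 to 5, in both replicates. Across 4525 IDR peaks with a region in both replicates' lists, the Spearman correlation of the replicate ranks was 0.917. This relation is across peaks, which are not independent replicates. The IDR peaks were also exactly the joint regions with the highest signal, and that signal pools these replicates. Agreement among them is therefore partly built in. The correlation was 0.939 over the 2267 stronger and 0.485 over the 2258 weaker of these peaks, where the replicates ordered the peaks less alike. The share depended on how many peaks were taken, from 90.7% for the strongest 2267 to 68.7% for the strongest 9068.

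EFL-1 lay mainly just upstream of genes. Of the IDR summits, 2681 (59.1%) fell within 500 bp of an annotated 5' end of a protein-coding transcript, against 23.03% ± 0.62 (SD) when peak positions were permuted at random within their chromosomes 1000 times (permutation p = 0.001, the smallest these can give). Of these near summits 89.6% lay on the upstream side. The median position over all of them was -149 bp, and the bin from -200 to -100 bp held the most, 838. Intergenic sequence held 72.7% of all summits and 37.3% of the genome. Coding exons held 1.37% of summits and 24.6% of the genome, introns 20.5% and 33.3%, 5' UTRs 4.12% and 1.43%, and 3' UTRs 1.35% and 3.32%. A further 15.6% of summits lay more than 2000 bp from any such 5' end. Many worm transcripts are trans-spliced, so an annotated 5' end can lie downstream of the site where transcription starts.

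**Figure D1:**
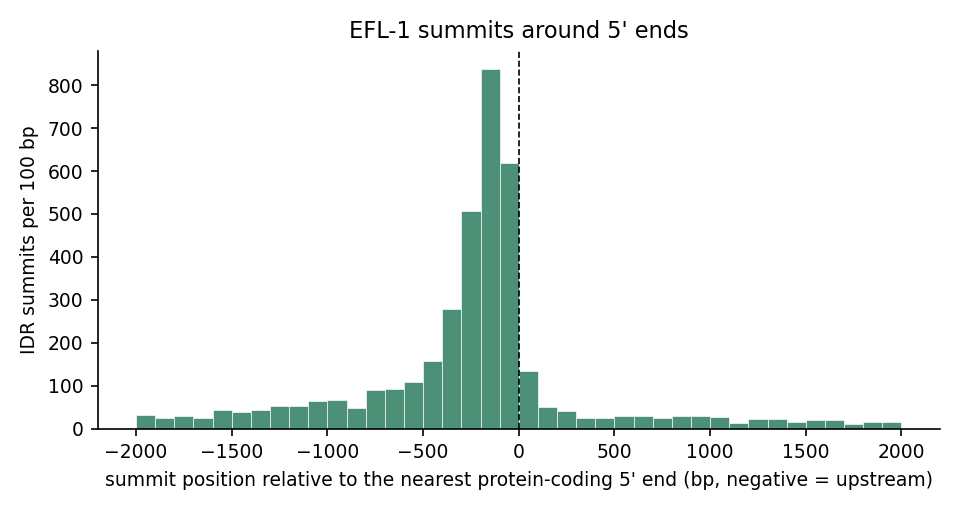
Number of IDR summits per 100 bp (y axis) by position relative to the nearest protein-coding 5' end (x axis, bp, negative upstream), for the authors' joint IDR list. The tallest bar, 838 summits, stands at -200 to -100 bp.

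Chromosomes I and III carried more EFL-1 peaks than their promoters would give, and chromosomes V and X fewer. Chromosome I held 904 peaks (19.9%, with 14.8% of protein-coding 5' ends) and chromosome III 896 (19.8%, with 13.4%). Chromosome V held 667 (14.7%, with 23.5% of 5' ends). The X chromosome held 522, which is 11.5% of the peaks (95% Clopper-Pearson interval 10.6 to 12.5) against 14.04% of 5' ends and 17.7% of the sequence (two-sided exact binomial test against the 5' ends, p = 5.57e-07, adjusted p = 8.35e-07 over 6 chromosomes). The replicates alone gave 11.6% and 11.7% on X. Chromosomes II and IV did not pass this binomial test (adjusted p = 0.905 and 0.852). Neighbouring peaks are not fully independent, so these p-values are too small.

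**Figure D2:**
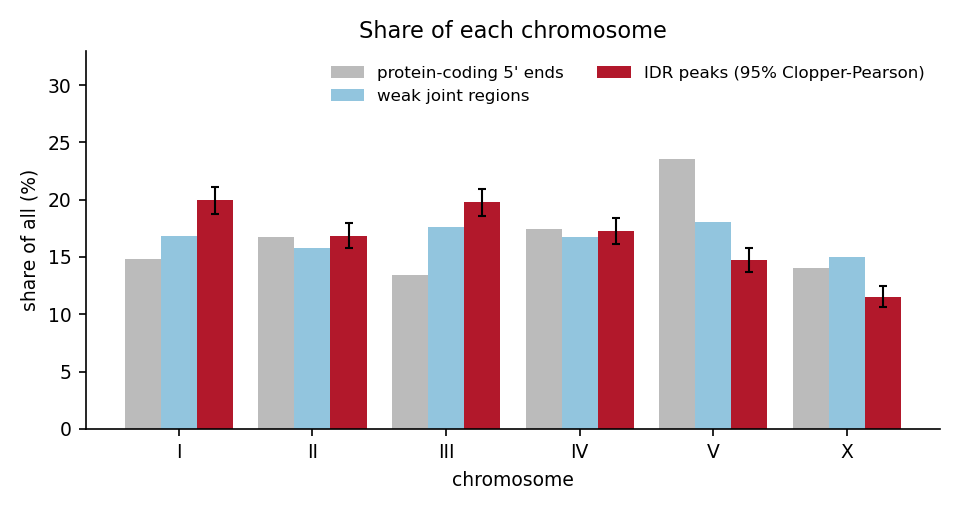
Share of protein-coding 5' ends, of weak joint regions outside the IDR list and of IDR peaks (y axis, percent) on each chromosome (x axis), with 95% Clopper-Pearson intervals on the IDR peaks. Chromosomes I and III stand above their share of 5' ends with 19.9% and 19.8% of IDR peaks, and X below it with 11.5%.

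The strongest peaks lay near genes of several kinds. The first, at chromosome III, 10759039 to 10759494, had its summit at -54 bp from the 5' end of tasp-1, a threonine aspartase gene, with a signal value of 9789 on the authors' scale, against a median of 125 over the IDR list. Next in rank came T23F6.3 (rank 2), F48A11.4 (rank 3), cdc-48.1, which encodes an AAA ATPase of protein turnover (rank 4), dld-1 for dihydrolipoamide dehydrogenase (rank 5) and mes-2, a histone H3 methyltransferase gene of the Polycomb type (rank 6). Ranks 8 and 9 belonged to the co-chaperone gene sti-1 and the importin gene imb-3. All 8 of these summits lay between protein-coding genes, at -54 to -261 bp. The rank 2 summit also lay just upstream of rbd-1 on the other strand, and the rank 5 summit inside the ncRNA gene LLC1.120. The peak of rank 7, at chromosome IV, 15570747 to 15571158, was far from any protein-coding 5' end, the summit lying at -6514 bp from Y105C5A.1. Within 500 bp of that summit lay the piRNA genes 21ur-8889 and 21ur-10547. The peak of rank 10 lay past the end of the neuropeptide-like gene nlp-40, with its summit 1923 bp downstream of the nearest annotated 5' end. Among the 10 summits 9 kept a rank of 11 or better in both replicates, and rank 7 of the joint list was rank 12 in replicate 2 and rank 6 in replicate 3.

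EFL-1 was bound at its own gene and at most genes of the DREAM complex, the assembly of E2F, DP, pocket protein and MuvB subunits. A gene was counted as bound when an IDR summit lay between 1000 bp upstream and 500 bp downstream of an annotated 5' end, and by this rule 6 of the 8 core genes were bound. The peak at efl-1 itself ranked 122 of 4534 (chromosome V, 16965708 to 16965997, summit at -180 bp). Higher still were lin-54 (rank 75, chromosome IV, 13240514 to 13240832, -364 bp) and lin-53 (rank 88, chromosome I, 9619837 to 9620155). The peak at lin-9 ranked 170, that at lin-35, the gene mutated in this strain, 505 (chromosome I, 5807378 to 5807666, -184 bp), and that at dpl-1, the DP partner of EFL-1, 1923. The replicate ranks were 113 and 134 at efl-1, 483 and 552 at lin-35, and 2152 and 1605 at dpl-1. At lin-52 the joint list held only a weak region outside the IDR list (rank 6026 of 21875, signal value 31.2), and at lin-37 no region lay in the window. The lin-54 peak was shared with rpl-12 on the other strand, from whose 5' end the summit lay at -29 bp. The peaks at efl-1, lin-35 and lin-53 also fell in the windows of fbxa-90, vps-51 and nra-2, so the gene acted on is not settled by position. A peak list shows where EFL-1 was, and the genotype cannot be checked from it.

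Genes of DNA replication and chromosome segregation were bound far more often than other genes. Over the genome, 3922 of 19973 protein-coding genes (19.6%) were bound. In the replication list 35 of 41 genes were bound (85.4%, odds ratio 24.1, 95% interval 10.1 to 57.3, adjusted exact p = 1.12e-18), led by pcn-1 for the sliding clamp PCNA (rank 50), the primase gene pri-2 (rank 56) and ctf-4 (rank 57). Of the mitosis, kinetochore and centrosome genes 52 of 55 were bound (94.5%, odds ratio 71.9, adjusted exact p = 1.35e-32), with the centriole gene sas-4 (rank 33), the kinetochore gene kbp-4 (rank 77) and the kinesin gene klp-18 (rank 134) strongest. The replicates alone gave 35 and 36 replication genes, and 52 mitosis genes each. Many of these peaks also lay in the window of a gene outside the list, 23 of the 35 for replication genes and 41 of the 52 for mitosis genes. With each peak given only to its nearest gene, 26 replication genes (odds ratio 10.2) and 34 mitosis genes (9.54) were bound, both still called. The mitosis odds ratio was 27.5 within 300 bp of the 5' end and 27.2 in the stronger 2267 peaks. DNA repair and checkpoint genes reached 27 of 48 (56.2%, odds ratio 5.29, adjusted exact p = 5.92e-08), led by top-2 for topoisomerase II (rank 89), hpr-17 (rank 96) and mrt-2 (rank 225), the last 2 of them checkpoint genes. Cell cycle regulators reached 17 of 32 (53.1%, odds ratio 4.65, adjusted exact p = 5.01e-05), with cdc-48.1 (rank 4), the cyclin E gene cye-1 (rank 113) and the CDK-inhibiting kinase gene wee-1.3 (rank 146) at the top. With nearest genes only, repair stood at 3.51 and cell cycle regulators at 3.06, both still called, as were cell cycle regulators within 300 bp (2.65). The tests here and for the lists that follow were two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 22 lists.

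Genes of housekeeping complexes were also bound far more often than other genes. Over the ribosomal protein, proteasome and nuclear pore lists 124 of 138 genes (89.9%) were bound, against 87 of 96 replication and mitosis genes (90.6%, odds ratio 0.92, 95% interval 0.38 to 2.21). This likeness depended on the window, since within 300 bp of the 5' end the shares were 55.1% and 76.04% (odds ratio 0.39, 95% interval 0.22 to 0.69). IDR summits marked 72 of 79 ribosomal protein genes (91.1%, odds ratio 42.9, 95% interval 19.7 to 93.2, adjusted exact p = 5.39e-42), on 69 separate peaks, with rpl-3 (rank 15), rpl-35 (rank 58) and rpl-12 (rank 75) strongest. In the proteasome list 29 of 33 genes were bound (87.9%, odds ratio 29.9, adjusted exact p = 2.26e-16), led by rpn-11 (rank 30), rpt-1 (rank 83) and rpn-5 (rank 180). The nuclear pore list had 23 of 26 (88.5%, odds ratio 31.6, adjusted exact p = 2.67e-13), led by npp-19 (rank 35), npp-22 (rank 41) and npp-23 (rank 51). Peaks shared with a gene outside the list were those of 48 of the 72 ribosomal, 22 of the 29 proteasome and 13 of the 23 nuclear pore genes. With each peak given only to its nearest gene, the ribosomal odds ratio was 6.70, the proteasome one 11.7 and the nuclear pore one 9.37, all still past the threshold. Within 300 bp these were 7.39, 9.23 and 10.9, again called, and in the stronger 2267 peaks the ribosomal and nuclear pore ones were 68.1 and 14.2.

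Chromatin genes and the synMuv B class, genes that repress vulval fates redundantly with other classes and include lin-35, were bound more often too. Among chromatin regulators 28 of 41 were bound (68.3%, odds ratio 8.87, adjusted exact p = 5.47e-11), with mes-2 (rank 6), mcd-1 (rank 78) and the ISWI remodeller gene isw-1 (rank 116) strongest. The DREAM and synMuv B list had 14 of 23 (60.9%, odds ratio 6.39, adjusted exact p = 3.67e-05), led by lin-54, lin-53 and efl-1, whose ranks are given above. The odds ratios were 5.58 and 4.50 with nearest genes only and 4.34 and 3.61 within 300 bp, all still called. In the stronger 2267 peaks the DREAM and synMuv B value was 9.73.

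Germline lists showed smaller excesses. Germ granule and small RNA genes reached 18 of 47 (38.3%, odds ratio 2.55, adjusted exact p = 0.00434), led by the mutator genes rde-2 (rank 165) and mut-15 (rank 229) and the double-stranded RNA binding gene rde-4 (rank 812). Meiosis genes reached 15 of 42 (35.7%, odds ratio 2.28, adjusted exact p = 0.0238), with the cohesin loader gene scc-2 (rank 126, in an intron and upstream of an internal 5' end), the kleisin gene coh-3 (rank 258) and rec-1 (rank 646) on top. Both calls ended when a peak counted only for its nearest gene (odds ratios 1.58 and 1.59), over deciles of upstream distance (1.89 and 1.51) and against named genes only (1.91 and 1.71). The meiosis call also ended without replicate 3 (1.85), within 300 bp (1.35) and in the stronger 2267 peaks (2.03). Peaks were shared with a gene outside the list at 13 of the 18 germ granule and 11 of the 15 meiosis genes. Among these were rde-2, mut-15, rde-4, coh-3 and rec-1. The list of germline RNA regulators and maternal factors was not called, at 13 of 47 (27.7%, odds ratio 1.57, adjusted exact p = 0.239), and its strongest member was the RNA helicase gene cgh-1 (rank 141).

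Several lists of tissue genes and large families were bound less often than other genes. In the intestine list 1 of 43 genes was bound (odds ratio 0.097, adjusted exact p = 0.003), erm-1 at rank 2480, and 2 without replicate 2 (0.203, still called). In the epidermis list 2 of 42 were bound (odds ratio 0.20, adjusted exact p = 0.0157), vab-10 at rank 939 and ajm-1 at rank 3011, both in introns of long genes. The major sperm protein genes had 0 of 31 bound (adjusted exact p = 0.00379), a count that by 3 counts of the total allows a share of up to 9.68%, and this call ended in the stronger 2267 peaks (adjusted exact p = 0.0657). Collagen genes had 10 of 156 (6.41%, odds ratio 0.28, adjusted exact p = 9.96e-06), with col-2 (rank 250), col-38 (rank 806) and col-71 (rank 997) strongest, on peaks that also lay in the windows of the kinetochore gene ndc-80, the ribosomal gene rpl-5 and Y49F6B.2. Within 300 bp 2 collagen genes were bound (0.087). Chemoreceptor genes had 14 of 1309 (1.07%, odds ratio 0.041, adjusted exact p = 1.47e-103), led by sri-5 (rank 143), srr-10 (rank 784) and srh-16 (rank 829), with the peak of sri-5 shared with rsr-1 and that of srr-10 with clic-1. Of the 14, 10 shared the peak with a gene outside the list. Sharing was also common in lists called high, with 41 of 52 mitosis genes and 12 of 28 chromatin regulators. The chemoreceptor odds ratio was 0.019 within 300 bp and 0.025 with nearest genes only. Nuclear hormone receptor genes had 39 of 269 (14.5%, odds ratio 0.69, adjusted exact p = 0.0473), with nhr-47 (rank 554, shared with dnj-19), nhr-142 (rank 576, shared with F44E7.9) and nhr-256 (rank 827) on top. This last call was lost without replicate 3 (odds ratio 0.78, adjusted exact p = 0.184), with nearest genes only (0.87, adjusted exact p = 0.537), over deciles of upstream distance (0.777) and under circular shifts (adjusted permutation p = 0.228). In the stronger 2267 peaks it was kept and larger (10 of 269, odds ratio 0.284, adjusted exact p = 8.45e-06). The epidermis call was lost with nearest genes only (0.29, adjusted exact p = 0.124), over deciles (0.245) and in the stronger 2267 peaks (0.181), but not within 300 bp (0.079).

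Muscle (11 of 45), neuron (10 of 51), cell death (6 of 27) and histone genes (16 of 72) did not pass the test in either direction, with odds ratios from 0.998 to 1.32 and adjusted p from 0.522 to 1. This does not show that they were bound at the genome's rate: over deciles of upstream distance muscle genes stood at 2.02 (95% interval 1.02 to 4.0) and histone genes at 0.56 (0.32 to 0.98), again not called. Their strongest bound members were the myosin chaperone gene unc-45 (rank 986), ric-19 (rank 661), icd-1 (rank 183) and his-37 (rank 189). The 16 bound histone genes rested on 10 separate peaks, since pairs such as his-67 and his-68 shared 1.

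**Figure D3:**
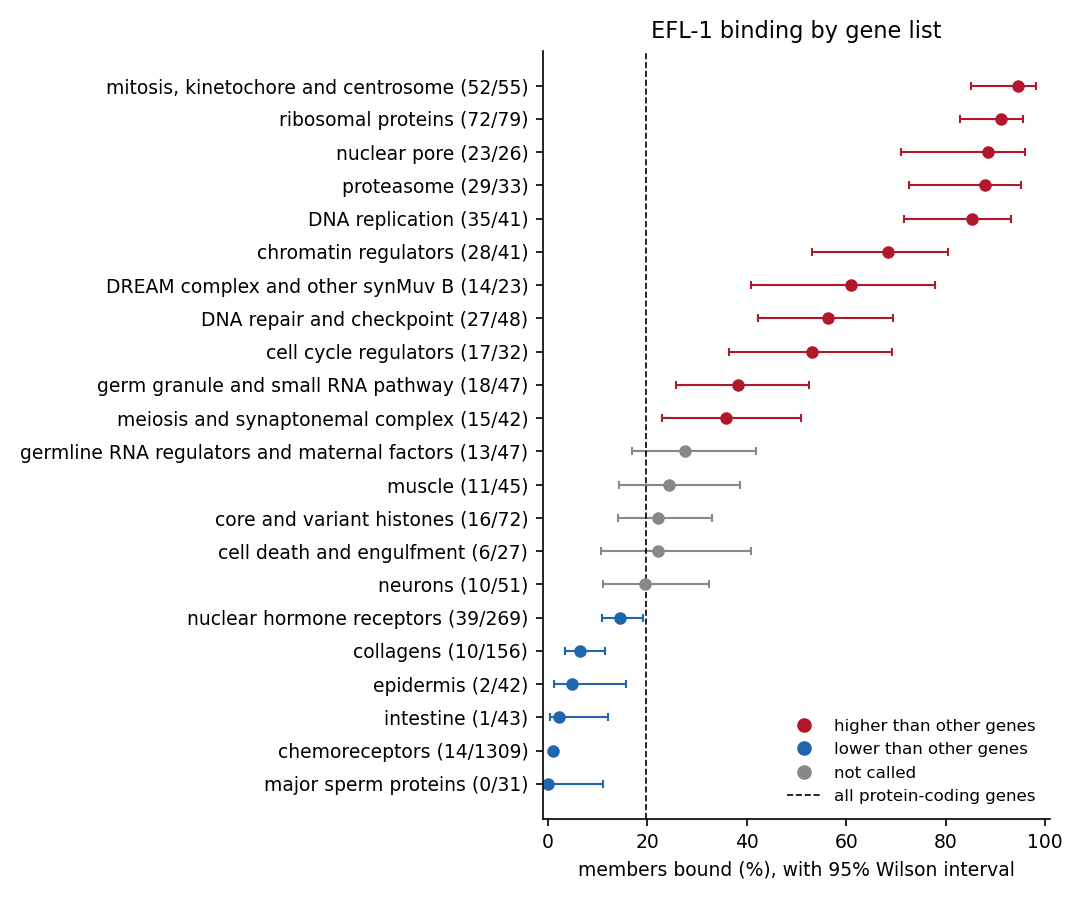
Percent of each list's genes with an IDR summit in the 5' window (x axis) for the 22 lists (y axis, bound and total genes in brackets), with 95% Wilson intervals; red lists were called higher, blue lower and grey not called, and the dashed line marks 19.6% over all protein-coding genes. Mitosis genes stand at 94.5%, ribosomal protein genes at 91.1% and chemoreceptor genes at 1.07%.

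Bound genes also differed in how strong their peaks were. The median percentile of the strongest assigned peak was 89.4 for bound ribosomal protein genes, against 59.6 for other bound genes (difference 29.7, adjusted p = 9e-05 by a two-sided permutation test with 100000 resamples). Chromatin regulators stood at 89.1 (difference 29.03, adjusted permutation p = 0.00468), the DREAM and synMuv B list at 87.9 (27.7, adjusted permutation p = 0.039), replication genes at 82.8 (22.8, adjusted permutation p = 0.0127) and mitosis genes at 79.3 (19.3, adjusted permutation p = 0.0127). Peaks were weaker at nuclear hormone receptor genes, with a median percentile of 26.8 (difference -33.8, adjusted permutation p = 9e-05), and at the 11 bound muscle genes, with 23.8 (difference -36.6, adjusted permutation p = 0.0133). Another 11 of the 18 lists with at least 10 bound genes did not pass. The DREAM and synMuv B call was lost on replicate 2's ranks alone (adjusted permutation p = 0.0514), and the muscle call on replicate 3's alone (adjusted permutation p = 0.0683).

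The E2F consensus TTTSSCGC was found within 100 bp of 437 summits (9.64%), against 3.61% of flanking windows 500 bp away (odds ratio 2.85, 95% interval 2.46 to 3.31, adjusted p = 1.41e-43 by two-sided Fisher's exact tests over 6 patterns). Most IDR peaks had no match to it. A GA repeat, GAGAGAGA, had the largest excess, at 604 summits (13.3%) against 1.32% of flanks (odds ratio 11.5, adjusted exact p = 1.59e-179). Its odds ratio was 6.52 within 200 bp of all summits. Against promoters with no IDR summit it was 5.18 (9.34% against 1.95%), over only the 3232 summits within 1000 bp of a 5' end. The GC box GGGCGG stood at 8.76% against 3.63% (odds ratio 2.55) and the E-box CACGTG at 6.24% against 3.94% (odds ratio 1.62). The CHR element TTYGAA, a site of the LIN-54 type of DREAM subunit, was less frequent at summits than in flanks (44.7% against 53.3%, odds ratio 0.71, adjusted exact p = 2.59e-21), as was the GATA site (28.7% against 35.5%, odds ratio 0.73). Letter-shuffled versions of the E2F pattern had a median odds ratio of 1.57, and 5 of 100 reached that of the real pattern, which ended the call (two-sided permutation p over letter orders 0.119). None of 69 shuffles reached the GA repeat, while all 4 shuffles exceeded the GC box, too few to pass the threshold. As high as the real pattern were 9 of 29 shuffles for CHR, 14 of 51 for the E-box and 51 of 100 for GATA. This ended all 3 calls (two-sided permutation p = 0.667, 0.577 and 0.99), and CHR stood at 1.05 times its shuffled median.

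E2F and CHR matches were most frequent at the strongest peaks. Among the strongest 454 peaks, E2F matches were present at 21.1% of summits and 3.74% of the peaks' own flanks. Among the other IDR peaks they stood at 8.36% of summits (odds ratio 2.94, 95% interval 2.29 to 3.78, adjusted exact p = 1.34e-14). CHR matches were present at 62.1% against 42.7% (odds ratio 2.2, 95% interval 1.80 to 2.68, adjusted exact p = 1.34e-14), and there they also exceeded the peaks' own flanks (48.9%). The GA repeat went the other way, with 9.25% among the strongest 454 and 13.8% elsewhere (odds ratio 0.64, adjusted exact p = 0.00968). This split was made after the data were examined, and these p-values come from two-sided Fisher's exact tests adjusted over 14 comparisons. Against letter-shuffled patterns neither the E2F nor the CHR contrast passed (two-sided permutation p = 0.0594 and 0.0667). For CHR this was the smallest p that its 29 shuffles can give. Among the DREAM core genes, the peaks at efl-1, lin-9, lin-53 and lin-54 held both an E2F and a CHR match, that at dpl-1 a CHR match alone, and that at lin-35 neither.

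**Figure D4:**
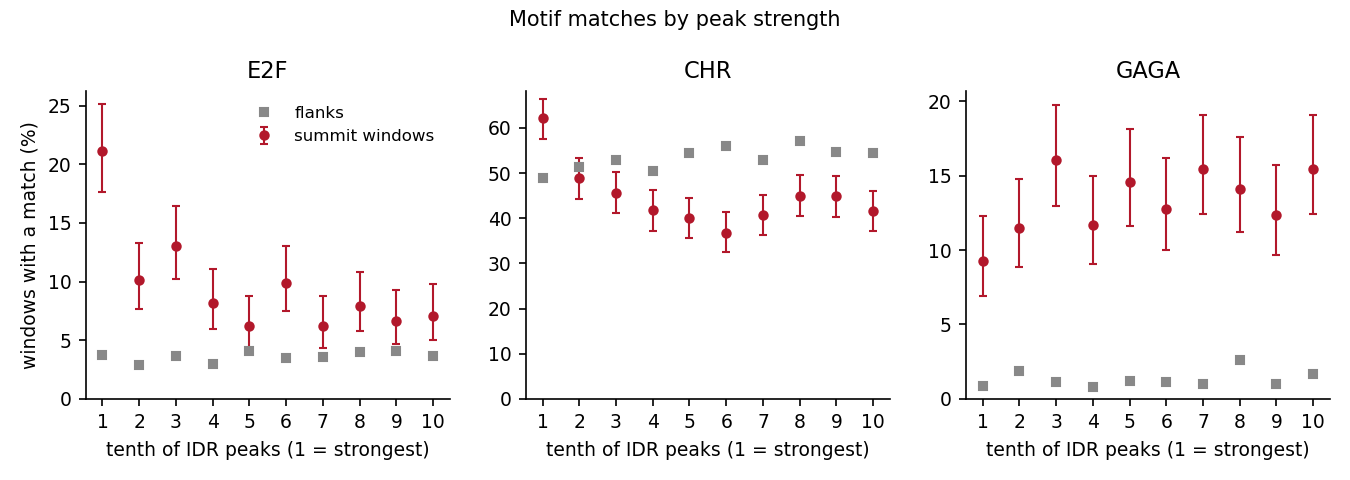
Percent of windows with an E2F, CHR or GAGA match (y axes, each from 0) in 10 equal groups of the IDR peaks by signal value (x axes, 1 the strongest), for summit windows with 95% Wilson intervals (red) and for their flanks (grey squares). E2F stands at 21.1% and CHR at 62.1% in the strongest group, both above the other 9 groups.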

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

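The tests that use weak regions, on X, on E2F matches and on gene lists, and the E2F tests of single housekeeping lists were chosen after related values had been seen. The other predictions were written first, on patterns already noticed in these data. The design has 1 group, so no biological explanation that needs a comparison of groups was tested.

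The 17341 joint regions outside the IDR list, whose sequence no comparison above uses, also carried E2F matches above their surroundings. Matches stood at 4.60% of their summits and 3.38% of their flanks, an odds ratio of 1.38 (95% interval 1.26 to 1.51, adjusted p = 1.66e-11 over 6 patterns by two-sided Fisher's exact tests). The GA repeat (2.67), the GC box (1.56) and the E-box (1.46) had larger odds ratios at the same regions, so the excess was not particular to E2F. No control library was compared, the flanks were the only reference, and base composition was not taken out. Of the 21875 joint regions 6596 had a −log10 q value over 2, all IDR peaks among them. Most of the weak regions may therefore be background, and a weak region is not read as binding here. Among genes without an IDR summit, all 6 remaining replication genes had a weak region in their window (adjusted exact p = 0.00336 over 22 lists), as did 21 of 34 muscle genes (adjusted exact p = 0.000557) and 21 of 41 neuron genes (adjusted exact p = 0.00799), against about 27.7% of other such genes. Cell cycle (9 of 15, adjusted exact p = 0.0251), ribosomal (5 of 7, adjusted exact p = 0.0452) and nuclear hormone receptor genes (82 of 230, adjusted exact p = 0.0251) were higher too, the last against the direction of its IDR call. Lower were chemoreceptors (132 of 1295, adjusted exact p = 8.18e-57), and collagens (26 of 146), histones (7 of 56) and major sperm proteins (2 of 31), each with an adjusted exact p of 0.0251.

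Ribosomal protein, proteasome and nuclear pore genes were bound about as often as replication and mitosis genes in the wide window (89.9% and 90.6%), and with nearest genes only (57.97% and 62.5%, odds ratio 0.83, 95% interval 0.49 to 1.41). Within 300 bp of the 5' end they were bound less often (55.1% and 76.04%, 0.39, 0.22 to 0.69), so the equal rate does not hold near the 5' end. As a cause of their excess over other genes, compact gene neighbourhoods, in which a neighbour's peak falls in the window, are argued against as the whole explanation: with nearest genes only, or over deciles of upstream distance, the lowest lower 95% bound of the 3 odds ratios was 4.25. An equal supply of E2F sites is argued against by the sequence for the 3 lists together. E2F matches were present at 10.9% of the peaks of these lists (13 of them) and 44.7% of those of replication and mitosis (38), with an upper 95% bound of the odds ratio of 0.311. The lists differed, however, with matches at 2 of 68 ribosomal, 5 of 29 proteasome and 6 of 22 nuclear pore peaks, leaving out peaks shared with replication and mitosis genes. The upper 95% bounds of their odds ratios were 0.163, 0.739 and 1.301, so for nuclear pore genes an equal supply stays open. Against IDR peaks of none of these 5 lists (8.92%) the odds ratios were 0.31 (95% interval 0.08 to 1.27), 2.13 (0.81 to 5.61) and 3.83 (1.49 to 9.84). Binding through other factors at open promoters may account for this, a hypothesis with no test here, since accessibility and expression were not analysed here.

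The X chromosome held fewer IDR peaks than its promoters would give. Weak joint regions lay on X more often (15.02%) than IDR peaks (11.5%), with an upper 95% bound of the odds ratio of 0.814. This does not decide whether signal was lower over all of X. The IDR list is the top of the joint list by signal, so a lower signal on X would also move its peaks to the weak regions, and the median percentile was 40.97 for IDR peaks on X and 51.5 on the autosomes. Genes of the lists called high were rarer on X (0.513% of its genes, against 2.63% on autosomes). Whether such a shortage was the whole cause is not decided by the members themselves. Of these, 6 of 14 on X and 324 of 453 on autosomes were bound. The odds ratio was 0.299 (95% interval 0.10 to 0.88), the result predicted if it was not the whole cause, but 14 genes are few. The lists were pooled, though their bound shares ran from 35.7% to 94.5%. A different mix of lists on X could therefore give such a gap. Over all genes 12.1% on X and 20.8% on autosomes were bound (odds ratio 0.524). Outside the lists called high these were 11.96% and 19.5% (0.562), and outside the lists called low 12.3% and 22.8% (0.475), so leaving out neither set removed the gap.

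E2F and CHR matches were concentrated in the strongest 454 IDR peaks. GC and CpG content alone are argued against: within groups of equal GC content, or of equal CpG count, the lowest lower 95% bound of the odds ratio was 2.04 for E2F and 1.83 for CHR. Letter shuffles did not settle whether other patterns of the same letters would do as well. As high an odds ratio came from 2% of 100 shuffled E2F patterns (two-sided permutation p = 0.0594, 1 shuffle reaching 3.98) and 0% of 29 shuffled CHR patterns, too few for a two-sided permutation p under 0.0667. Fewer than 5% had been set beforehand as enough against base composition, but that bound was looser than the two-sided p used for the whole list. Genes of the replication, cell cycle, mitosis, repair and meiosis lists do not account for it alone: without the 151 peaks in their windows, the lower 95% bound of the odds ratio was 1.91 for E2F and 1.70 for CHR. A candidate explanation is that direct DREAM-type binding makes the strongest peaks and that many weaker ones arise in another way. That remains open, because other DREAM subunits were not analysed here and peak position was not taken out. Summits within 500 bp of a 5' end fell from 78.6% of the strongest 454 peaks to 44.8% of the weakest 453. E2F and CHR matches were present at 10.2% and 49.4% of peaks inside gene windows, and at 8.35% and 34.3% outside, differences that were not tested. All animals also carried lin-35(n745), a mutation in the gene for the pocket protein of DREAM, so an intact complex cannot be assumed.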

How the results depend on the processing

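Of 311 alternatives of the main results 264 kept their direction and side of the threshold (for values without a test, their interval). The named genes have no test. The peaks of those that were bound all lay within the top 4534 regions of each replicate's own list, the lowest at rank 3835, in 122 comparisons. This was likely beforehand, since most were named for strong peaks. Of all IDR peaks 95.1% and 91.3% lay in the top 4534 of replicates 2 and 3. The genes lin-37 and lin-52 had no IDR peak and were left out of these comparisons. The share on X against genes in place of 5' ends, and the strongest 454 peaks, were chosen after seeing the data. Causes were not tested unless given. With nearest genes only, calls were lost for germ granule (odds ratio 1.58), meiosis (1.59), epidermis (0.291) and nuclear hormone receptor genes (0.870). Over deciles of upstream distance these stood at 1.89, 1.51, 0.245 and 0.777, again not called. Against named genes only, germ granule (1.91) and meiosis (1.71) were not called. Within 300 bp of the 5' end meiosis fell to 1.35. In the stronger 2267 peaks meiosis (2.03), epidermis (0.181) and major sperm proteins (0.118) were not called, with fewer bound genes to test. Circular shifts left the nuclear hormone receptor value at 0.691 and ended its call. Leaving out each replicate gave 1.85 to 2.57 for meiosis and 0.559 to 0.780 for nuclear hormone receptors, each not called without replicate 3. Differences in peak strength, as percentiles of the longer replicate lists and so on a narrower scale, were 4.73 with either replicate left out for DREAM and synMuv B, lost without replicate 3, and -6.96 to -4.86 for muscle, lost without replicate 2. Odds ratios of lists not called crossed 1 and stayed not called. With nearest genes only neurons stood at 1.42 and histones at 0.940, and over deciles at 1.26 and 0.560. Against named genes muscle stood at 0.993, cell death at 0.876 and histones at 0.876, and within 300 bp germline RNA at 0.804 and muscle at 0.844. In the stronger peaks cell death stood at 0.931, muscle at 0.531 and histones at 0.676. Leaving out each replicate gave 0.893 to 1.004 for neurons, 0.993 to 1.006 for histones and, in peak strength, -0.757 to 0.162 for chemoreceptors.

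Relative to the median of letter-shuffled patterns, E2F (1.82, with 5 of 100 shuffles as high), E-box (1.33) and GATA (0.996) were no longer called. CHR (1.05) and GC box (0.736, with 4 shuffles only) fell on the other side of 1, neither called. Within 200 bp of the summit GATA stood at 0.971 and was not called. In the strongest 454 peaks CHR was above its flanks (1.71), while GC box (1.41) and E-box (1.09) were not called. Replicate overlap was 76.3% with 50% reciprocal overlap, 85.1% for summits within 100 bp, 90.7% for the top 2267 and 68.7% for the top 9068. Depth is unknown, so a gene counted as not bound had no summit above the authors' threshold, and weaker binding there is not excluded.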

Other observations

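The tests in this part were all chosen after the data were examined.

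The peaks of different gene groups differed in sequence. E2F matches were present at 17 of 35 replication peaks (48.6%, against 9.34% of other IDR peaks, odds ratio 9.17, adjusted exact p = 9.43e-08), at 21 of 52 mitosis peaks (40.4%, odds ratio 6.62, adjusted exact p = 9.43e-08), at 7 of 14 DREAM and synMuv B peaks (odds ratio 9.51, adjusted exact p = 0.000936), at 8 of 27 repair peaks (29.6%, odds ratio 4.0, adjusted exact p = 0.0146) and at 4 of 10 collagen peaks (odds ratio 6.30, adjusted exact p = 0.0449). Of the bound genes of these lists, in the same order, 23, 41, 6, 17 and 4 shared the peak with a gene outside the list. The peak of col-2, which held an E2F match, was shared with the kinetochore gene ndc-80. Not called were nuclear pore peaks (6 of 23, odds ratio 3.34, adjusted exact p = 0.0637), proteasome peaks (5 of 29, odds ratio 1.964, adjusted exact p = 0.307) and ribosomal protein peaks (2 of 69, odds ratio 0.28, adjusted exact p = 0.136), here with shared peaks kept and all other IDR peaks as reference. Cell cycle (3 of 17, odds ratio 2.02, adjusted exact p = 0.332) and meiosis peaks (1 of 15, odds ratio 0.67, adjusted exact p = 1) were not called either, nor were the other lists. CHR matches were frequent at several groups, with 82.7% of mitosis peaks (odds ratio 6.02, adjusted exact p = 3.74e-07), 85.2% of repair peaks (odds ratio 7.19, adjusted exact p = 0.000251) and 77.1% of replication peaks (odds ratio 4.22, adjusted exact p = 0.000882). They were also frequent at cell cycle peaks (14 of 17, adjusted exact p = 0.0124), DREAM and synMuv B peaks (11 of 14, adjusted exact p = 0.0493), nuclear pore peaks (20 of 23, adjusted exact p = 0.0006) and proteasome peaks (22 of 29, adjusted exact p = 0.00625), and stood at 49.3% at ribosomal protein peaks (adjusted exact p = 0.598). The GA repeat was present at 0 of 69 ribosomal protein peaks, which allows a share of up to 4.35%, against 13.5% of the others (adjusted exact p = 0.000866). It was low as well at 0 of 35 replication peaks, which allows up to 8.57%, and at 1 of 52 mitosis peaks (adjusted exact p = 0.0449 for each). These are two-sided Fisher's exact tests adjusted over 54 pairs of list and pattern. Over all IDR peaks, a CHR match was more frequent with an E2F match than without 1 (62.9% against 42.7%, odds ratio 2.27, adjusted exact p = 4.68e-15).

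A scan of 175 gene families with at least 10 members of the same symbol prefix found 30 bound more often and 43 less often than other genes at an adjusted p under 0.05. Beyond the lists fixed earlier, the higher families included eif translation initiation factors (19 of 25, odds ratio 13.02, adjusted exact p = 3.59e-08), vps genes of vacuolar sorting (19 of 31, odds ratio 6.51), mitochondrial ribosomal mrps (18 of 29, odds ratio 6.72) and mrpl genes (21 of 41, odds ratio 4.31), cox genes of cytochrome oxidase (11 of 15, odds ratio 11.3), vha genes of the vacuolar ATPase (13 of 20, odds ratio 7.62) and rpb genes of RNA polymerase II (9 of 11, odds ratio 18.5). Lower families included clec C-type lectins (5 of 240, odds ratio 0.086, adjusted exact p = 4.78e-15) and lgc ligand-gated channels (0 of 56, which allows a share of up to 5.36%, adjusted exact p = 7.8e-05).

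Of 9 classes of non-coding genes 6 had EFL-1 summits near them more often than random placement gives. Summits lay within 500 bp of the 5' end of 167 of 612 tRNA genes (27.3%, against 3.96% ± 0.86, SD of 1000 random placements) and of 116 of 346 snoRNA genes (33.5%, against 4.70% ± 1.23). The shares were 19.4% for snRNA, 13.03% for miRNA, 12.9% for lincRNA and 10.8% for other ncRNA genes, against 4.06 to 4.53% at random. Each of the 6 had an adjusted permutation p of 0.0015 over 9 classes. Random placement did not keep the summits' preference for intergenic sequence (72.7% of summits, 37.3% of the genome), which could give part of such an excess. No control library was compared either. Among those more than 1000 bp from any protein-coding 5' end the shares were 24.8% (96 of 387 tRNA genes), 27.98% (54 of 193 snoRNA genes), 13.2% (snRNA), 10.5% (miRNA), 9.85% (lincRNA) and 7.37% (ncRNA). The shares over all genes of the class were 1.52% for piRNA genes (random 4.35%) and 2.30% for pseudogenes (random 4.08%), and this one-sided test was for an excess only. Of the rRNA genes 0 of 20 had a summit near (random 3.72%), and 20 genes are few.

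The 1414 IDR peaks outside every gene window (31.2%) were weaker than the rest, with a median percentile of 38.5 against 55.9. Their E2F share was 8.35% against 10.2% inside windows, their CHR share 34.3% against 49.4%, and their GA repeat share 22.8% against 9.01%. These differences were not tested.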
